A study of Rattus norvegicus with 58 samples.

How the data were processed

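Messenger RNA was measured in liver and kidney of male Harlan Sprague-Dawley rats given 4-methylcyclohexanemethanol (MCHM) by gavage for 5 days, with 1 Affymetrix rat genome array per organ sample. The deposited table holds 1 log2 value per probe set and array, made with RMA, a method that summarises the probes of a set, per the submitters' processing notes, which name it without a version. Whether liver and kidney arrays were normalized together is not given in the sources used here. The log2 scale was read from the values, which ran from 1.75 to 14.85 with 0 missing. The table held 31099 probe sets on 58 arrays, and 0 sample columns were left unmapped. Array medians lay between 5.26 and 5.32 in liver and between 5.33 and 5.38 in kidney. An array has no read depth, so the number of arrays per group limits the precision.

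Probe sets were named through the platform annotation given with the table. Of the probe sets, 57 were Affymetrix controls, 20826 had 1 gene symbol, 436 had several symbols and 9780 had no symbol there. The 1-symbol probe sets named 14217 genes. The gene identifier of 20764 of them was found in the rat gene table of assembly GRCr8, and 0 of those had another symbol there. A probe set was kept in an organ if its value was above its own array's 40th percentile on at least 4 arrays of that organ. This left 20028 probe sets in liver and 19675 in kidney. Of several probe sets of a gene, the brightest over the organ's arrays stood for the gene, so that 11275 genes were tested in liver and 11204 in kidney. For the difference between organs the brightest over all 58 arrays was used, with 10673 genes tested, so that a gene can rest on another probe set there.

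Groups and replicate numbers were taken from the sample titles. The labels call the arrays of a group biological replicates, and they name no batch and do not tie a liver to the kidney of the same rat. Each dose was compared with the 0 mg/kg group of the same organ in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with an intensity trend), with 1 fit per organ over all 29 arrays. A call is a Benjamini-Hochberg adjusted p under 0.05 within a comparison, two-sided. The dose trend used the dose rank as a single numeric term. The difference between organs was the contrast of the liver effect minus the kidney effect in a single fit with 14 groups. Fold changes are differences of group means on the log2 scale, with the standard error (SE) of the fit, and group values are given as mean ± SD.

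Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists of an organ and dose. Of the 33 lists, 27 had at least 5 measured genes in each organ and were tested. Camera compares a list with the other genes. Beside it stand camera with the correlation estimated from the residuals of each list, and fry, which tests whether the genes of a list move on balance in a single direction. As a description of list means per array, an exact permutation of the 9 arrays of a dose and the control (126 splits) was added after the data had been seen.

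The design, the lists, the filter, the alternatives and the rule for the genes named in the text were fixed before the data were examined. The rule took, at 500 mg/kg, the 10 largest rises and 10 largest falls among called genes with every dosed array on the same side of the control mean. At other doses with calls it took the 5 largest each way, for the dose trend the 5 smallest p each way, and for the difference between organs the 5 largest each way. Where a comparison had no call it took the 3 genes with the smallest p. From each list it took up to 4 measured members with the smallest p at 500 mg/kg, and the text gives a selection of these.

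Array quality was checked with the 3' minus 5' difference of the actin and GAPDH control probe sets, spike-in controls, the correlation with the group median and the share of probe sets above the pooled 40th percentile, each compared with control by exact permutation. Pairs of arrays were checked for identical values. Alternatives were no filter and a stricter filter (60th percentile), the mean over a gene's probe sets, all probe sets, only the compared groups in the fit, eBayes without the trend and robust eBayes, array quality weights, quantile or cyclic loess normalization within the organ, the replicate number as a block, a 1.5-fold minimum, dose as a linear term and each array left out in turn. Chosen after the data had been seen were the fit without 2 kidney arrays with high adipose transcripts, a random block of dose and replicate number for the difference between organs, and the macrophage and lymphocyte list means without RT1-Ba. Every count of calls was also computed over 100 splits of the same arrays, the real split included.

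The fits were tested on simulated data with the real genes' means and spreads and known changes. At a log2 change of 0.5 the simulated 500 mg/kg comparison called 77.6% of 67 changed genes in liver (11275 genes in the fit) and 79.1% in kidney (11204 genes). At a log2 change of 1 it called 97% in liver and 100% in kidney. The simulated difference between organs called 59.7% at 0.5 and 91% at 1 (10673 genes). Unchanged genes called numbered 10, 8 and 4 in the liver, the kidney and the difference. Each simulation changed 67 genes by 0.5, 67 by 1 and 66 by 2 together, and those of a single organ at 500 mg/kg also lowered the cell cycle list. Every gene was drawn independently, which leaves out correlation between genes. The shares called therefore need not hold for the real arrays, and a missing call does not exclude a change of 0.5. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.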

Results

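MCHM is an alicyclic alcohol used industrially to wash coal. Livers and kidneys of male rats were profiled after 5 days of gavage at 0, 0.1, 1, 10, 100, 300 or 500 mg/kg. Each organ had 5 control arrays and 4 arrays at each of the 6 doses, 29 arrays per organ and 58 in all. The values are deposited log2 RMA values per probe set, and the arrays' medians spanned 5.26 to 5.38. The design asks which transcripts differ from the control of the same organ at each dose, which follow the dose, and where liver and kidney differ in their response.

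Of 60 exact permutation comparisons of quality measures with control, 2 had an exact p under 0.05. Both were kidney actin 3' minus 5' differences, higher than control by 0.08 at 0.1 mg/kg (exact p = 0.00794) and by 0.06 at 10 mg/kg (exact p = 0.0159), and neither passed the adjustment over the 60 (adjusted p = 0.476). Within an organ the highest correlation between a pair of arrays was 0.994 in liver and 0.996 in kidney, and no pair was identical.

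In liver, 0 genes passed limma's adjusted test at 0.1, 1, 10 or 100 mg/kg. At an unadjusted p under 0.05 there were 462, 657, 721 and 415 genes in that order, where 564 would be expected by chance. The genes with the smallest p follow as values. Bcar3, an adaptor protein of integrin signalling, was at 6.98 ± 0.22 (SD, n = 5) in controls. It was higher by 0.62 (SE 0.13, adjusted p = 0.574) at 0.1 mg/kg, by 0.59 (adjusted p = 0.351) at 1 mg/kg and by 0.69 (adjusted p = 0.126) at 10 mg/kg on the log2 scale. Ptpn23 and Sprn differed by -0.49 and 0.37 at 0.1 mg/kg (adjusted p = 0.998 for both). Ugp2, which makes UDP-glucose, and the B cell marker Ms4a1 differed by 0.36 and 0.80 at 1 mg/kg (adjusted p = 0.351 for both). Ube2t and Tnfrsf4 differed by -0.66 (adjusted p = 0.332) and -0.35 (adjusted p = 0.694) at 10 mg/kg. At 100 mg/kg the values were -0.58 for Gnpda1, 0.43 for Tm7sf2 and -0.35 for Pld4 (adjusted p = 0.999 for each). Array quality weights gave 1 call at 10 mg/kg, and the fit of the compared groups alone gave 2.

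At 300 mg/kg the liver showed 3 calls. Tm7sf2, a sterol reductase of cholesterol synthesis, rose from 10.47 ± 0.12 (SD, n = 5) to 11.21 ± 0.09 (SD, n = 4), a log2 change of 0.73 (SE 0.11, adjusted p = 0.00695). Cyp3a23-3a1, a drug-metabolising cytochrome P450 inducible through the nuclear receptor PXR, rose by 0.49 (SE 0.08, adjusted p = 0.0138). Lmcd1, a LIM domain protein, fell by 0.79 (SE 0.14, adjusted p = 0.0138). All 4 dosed arrays lay on the same side of the control mean for each. Without the third array at 300 mg/kg the number of calls was 0, with Tm7sf2 at 0.69 (SE 0.12, adjusted p = 0.0792), Cyp3a23-3a1 at 0.46 (SE 0.09, adjusted p = 0.172) and Lmcd1 at -0.65 (SE 0.14, adjusted p = 0.173). Without the second array it was 6. At an unadjusted p under 0.05 there were 890 genes, the called ones included, against 564 by chance.

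At the list level the preset camera test put 7 lists past the threshold in liver at 300 mg/kg. With an estimated correlation 0 of 27 lists passed (2 at an unadjusted p under 0.05), and with fry 0 (5 at an unadjusted p under 0.05). Of 20 cholesterol synthesis and uptake genes 1 rose, or 2 adjusted over the list alone, and 19 had a value above 0 (median 0.21, adjusted p = 2.49e-08, adjusted p = 0.325 with an estimated correlation). Of 20 targets of the receptors CAR and PXR 1 rose, or 3 adjusted over the list alone (median 0.12, adjusted p = 9.71e-06, adjusted p = 0.0934 with an estimated correlation). In the other called lists 0 genes passed over all genes tested. The medians were 0.23 for fatty acid synthesis (adjusted p = 0.000271), 0.11 for Nrf2 targets (adjusted p = 0.00045) and 0.13 for interferon response genes (adjusted p = 0.0264). They were -0.16 for the cell cycle (adjusted p = 7.8e-06) and -0.17 for macrophage and lymphocyte markers (adjusted p = 0.00045). With an estimated correlation these became an adjusted p = 0.325 for each except interferon response, at an adjusted p = 0.859.

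At 500 mg/kg the liver showed 108 calls, 55 higher and 53 lower, of which 34 reached 1.5-fold. The named rises include enzymes of amino acid and lipid metabolism. Tat, a tyrosine-degrading aminotransferase, rose by 1.39 (SE 0.29, adjusted p = 0.0191), from 8.67 ± 0.30 (SD, n = 5) to 10.05 ± 0.51 (SD, n = 4). Gpt, alanine aminotransferase, rose by 1.22 (SE 0.18, adjusted p = 0.00105), from 8.57 ± 0.19 to 9.78 ± 0.19. Noct, a circadian phosphatase, rose by 1.72 (SE 0.40, adjusted p = 0.0349). The fatty acid elongase Elovl6 rose by 1.28 (adjusted p = 0.0245), the citrate-cleaving enzyme Acly by 0.90 (adjusted p = 0.0165) and fatty acid synthase Fasn by 0.80 (adjusted p = 0.0308). The medium-chain acyl-CoA synthetase Acsm2 rose by 0.97, the carboxylesterase Ces2c by 0.81, Bdh2 by 0.80 and Spmip11 by 0.78, with adjusted p between 0.00515 and 0.0312 for these 4. Each named gene lay on its side of the control mean on all 4 dosed arrays.

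The named falls at 500 mg/kg follow. Cav2, a caveolin, fell by 0.85 (SE 0.13, adjusted p = 0.00105), from 8.04 ± 0.15 (SD, n = 5) to 7.19 ± 0.17 (SD, n = 4). Its 3 other probe sets differed by -0.34, -0.90 and -0.66. Cyclin D1, Ccnd1, fell by 0.91 (SE 0.22, adjusted p = 0.041). The mitotic spindle gene Nusap1 fell by 0.70 (SE 0.16, adjusted p = 0.0245) and the ubiquitin-conjugating enzyme Ube2t by 0.64 (SE 0.14, adjusted p = 0.0232). The protease inhibitor Slpi fell by 0.78 (adjusted p = 0.00515), Tent5c by 0.83 (adjusted p = 0.0191), Enc1 by 0.78 (adjusted p = 0.0435), Plcxd2 by 0.76 (adjusted p = 0.041) and Etfbkmt by 0.61 (adjusted p = 0.0359). The other probe set of Etfbkmt differed by -0.23. The immunoglobulin joining chain gene Jchain fell by 0.87 (adjusted p = 0.0348), while its other probe set differed by 0.10. Of the named genes, Gpt, Ces2c, Cav2, Slpi, Tm7sf2, Ehhadh, Cyp3a23-3a1 and Cyp3a18 were called in all 19 alternatives. The others lost their call in some. Ccnd1 did so in 13 of 19, Enc1 in 12, Plcxd2 and Srxn1 in 10, and Noct, Etfbkmt, Ebp and Cd74 in 9. The number of calls ranged from 33 with the replicate number as a block, or 42 without the first array at 500 mg/kg, to 263 with array quality weights.

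**Figure D1:**
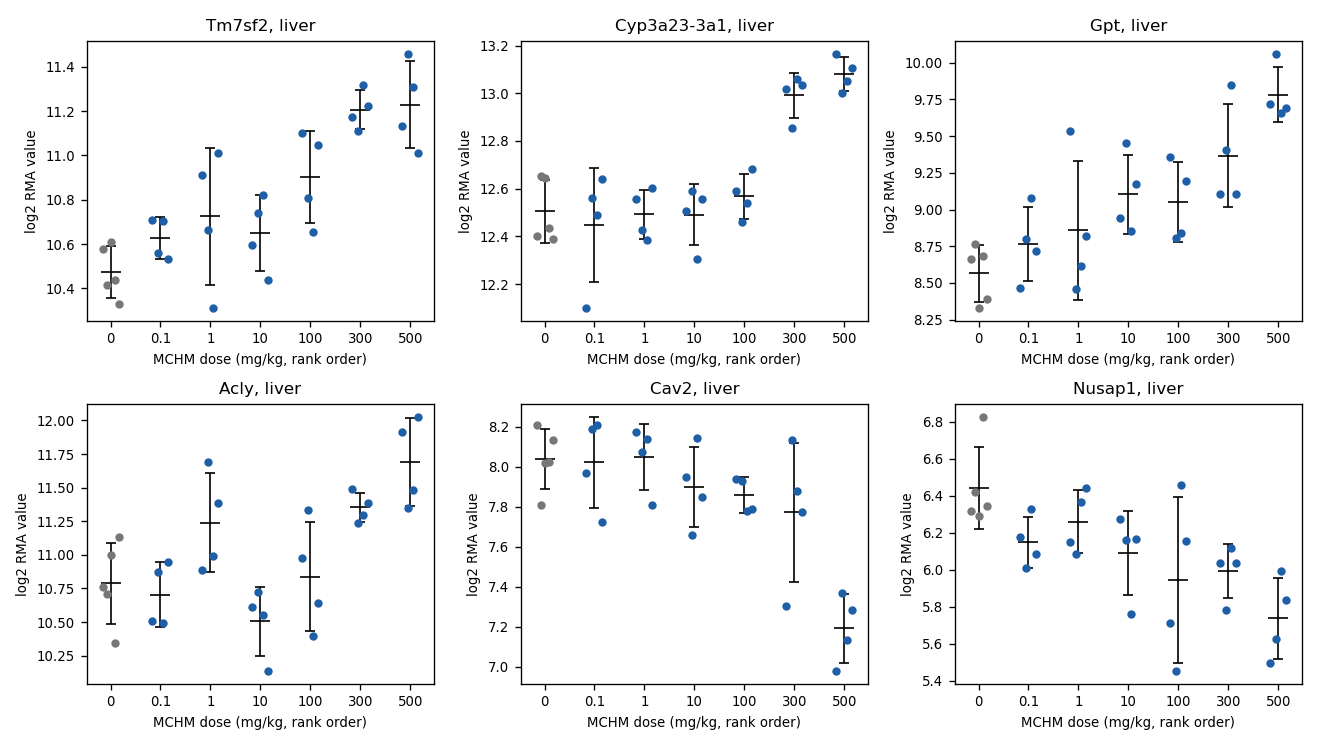
Liver log2 RMA values of 6 genes by MCHM dose in mg/kg, with doses drawn in rank order at equal spacing. Points are arrays (grey 0 mg/kg, blue dosed), the bars are the mean ± SD, and at 500 mg/kg all 4 points of Tm7sf2, Cyp3a23-3a1, Gpt and Acly lie above, and those of Cav2 and Nusap1 below, the control mean.

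In liver at 500 mg/kg the preset camera test called 6 of 27 lists, with an estimated correlation 0 passed (5 at an unadjusted p under 0.05), and with fry 4. Of 16 fatty acid synthesis genes 3 rose (Acly, Elovl6 and Fasn), or 9 adjusted over the list alone, with a median of 0.52 (adjusted p = 3.11e-07, adjusted p = 0.115 with an estimated correlation). Thrsp, a lipogenic regulator, differed by 1.13 (adjusted p = 0.0921). Of 20 cholesterol genes 2 rose, or 4 adjusted over the list alone, and 19 had a value above 0 (median 0.31, adjusted p = 4.2e-09, adjusted p = 0.247 with an estimated correlation). These were Tm7sf2, by 0.75 (SE 0.11, adjusted p = 0.00105), and the sterol isomerase Ebp, by 0.39 (adjusted p = 0.0343). Insig1 and Dhcr7 differed by 0.94 (adjusted p = 0.0793) and 0.45 (adjusted p = 0.0931). The 4 lists past fry were fatty acid synthesis, CAR and PXR targets, the cell cycle and macrophage and lymphocyte markers (adjusted p = 0.0136 for each), and the cholesterol list had an adjusted p = 0.0525.

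Of 20 CAR and PXR targets 3 rose, or 5 adjusted over the list alone (median 0.13, adjusted p = 0.00127, adjusted p = 0.147 with an estimated correlation). They were Cyp3a23-3a1, by 0.58 (adjusted p = 0.00105), Cyp3a18, by 0.61 (adjusted p = 0.00105), and Ces2c, while Cyp2c6v1 differed by 0.15 (adjusted p = 0.153). Of 22 Nrf2 targets 1 rose, Srxn1, which reduces oxidised peroxiredoxins, by 0.56 (adjusted p = 0.0455; list median 0.12, adjusted p = 0.0142, adjusted p = 0.548 with an estimated correlation). The list of PPAR alpha targets and fatty acid oxidation did not pass (median 0.02, adjusted p = 0.458), although 3 of its 33 genes rose. These were the peroxisomal enzyme Ehhadh by 0.64 (adjusted p = 0.00787), the fatty acid hydroxylase Cyp4a1 by 0.69 (adjusted p = 0.0217) and the isomerase Eci1 by 0.64 (adjusted p = 0.0281). Angptl4, of the same list, differed by -0.94 (adjusted p = 0.103).

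Of 28 cell cycle genes 1 fell, Nusap1, or 12 adjusted over the list alone, and 2 had a value above 0 (median -0.32, adjusted p = 4.2e-09, adjusted p = 0.115 with an estimated correlation). Cdk1 and Mki67 differed by -0.97 (adjusted p = 0.066) and -0.99 (adjusted p = 0.0807). Of 18 macrophage and lymphocyte markers 1 fell, or 12 adjusted over the list alone (median -0.27, adjusted p = 7.97e-08, adjusted p = 0.115 with an estimated correlation). It was Cd74, the invariant chain of class II antigen presentation, which fell by 0.59 (adjusted p = 0.0374). RT1-Da and Csf1r differed by -0.53 (adjusted p = 0.071) and -0.25 (adjusted p = 0.0839). RT1-Ba differed by -2.06 (adjusted p = 0.0672) with an SD of 1.90 at 500 mg/kg, and its 3 other probe sets by 0.56, 0.11 and 0.02. The mean of the macrophage and lymphocyte list was lower by 0.32 on average, on 4 of 4 arrays (exact permutation p = 0.00794, the smallest possible with 126 splits, adjusted over 27 lists 0.107), and by 0.22 without RT1-Ba (exact permutation p = 0.0556). Endothelial and stromal markers, of other non-hepatocyte cells, had a median of -0.11 (adjusted p = 0.0536).

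**Figure D2:**
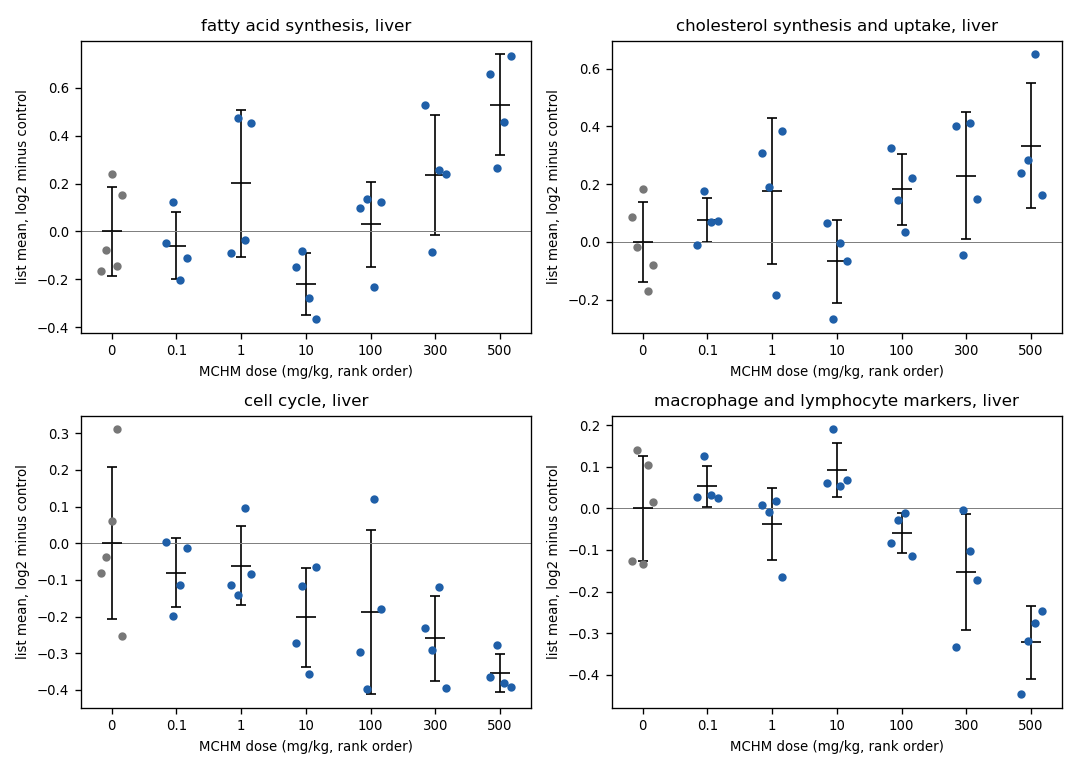
Mean of 4 gene lists on each liver array, as log2 minus the control mean, by MCHM dose in mg/kg drawn in rank order. Points are arrays (grey 0 mg/kg, blue dosed) and bars the mean ± SD, and at 500 mg/kg all 4 arrays lie above 0 for both lipid lists and below 0 for the cell cycle and the macrophage and lymphocyte lists.

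No other list passed in liver at 500 mg/kg, and several held single called genes. Among 24 acute phase genes Orm1, an alpha-1-acid glycoprotein, rose by 0.65 (adjusted p = 0.04), and A2m differed by -1.08 (adjusted p = 0.101, list adjusted p = 0.483). In limma over all probe sets, another probe set of Fga differed by -0.27 (adjusted p = 0.0244). The other probe sets of Cp differed by -0.34 (adjusted p = 0.0309) and 0.15 (adjusted p = 0.409), against 0.11 on the one used. Of 12 conjugation genes Acsm2 alone was called, and Ugt2b35 differed by -0.11 (list adjusted p = 0.458). Tat alone was called of 15 glucose metabolism genes (list adjusted p = 0.728), and Cyp3a18 alone of 11 male-biased genes (list adjusted p = 0.483). Of the remaining lists 0 members were called. In the stress response list Trib3 differed by 1.66 (SE 0.46, adjusted p = 0.0804; list adjusted p = 0.728), and in the immediate early list Egr1 by -2.32 (SE 0.63, adjusted p = 0.076; list adjusted p = 0.304). For AhR targets Cyp1a1 differed by 0.38 (list adjusted p = 0.398), for alcohol and aldehyde oxidation Aldh1b1 by -0.37 (list adjusted p = 0.902) and for p53 targets Bbc3 by 0.35 (list adjusted p = 0.458). For bile acid genes Slc27a5 differed by 0.37 and Abcg5 by -0.47 (list adjusted p = 0.398), for the circadian clock Npas2 by 0.28 (list adjusted p = 0.695) and for interferon response genes Rtp4 by -0.41 (list adjusted p = 0.458). Pericentral genes had a median of 0.07 (adjusted p = 0.739) and periportal genes of 0.01 (adjusted p = 0.389).

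The lists aimed at the kidney or at other tissues did not pass in liver at 500 mg/kg either. The medians were -0.09 for kidney injury markers (adjusted p = 0.0853), -0.06 for proximal tubule (adjusted p = 0.483), 0.06 for distal tubule (adjusted p = 0.728), -0.06 for glomerular (adjusted p = 0.458) and 0.02 for adipose markers (adjusted p = 0.855). The mean of the adipose list was -0.03, below 0 where its median and camera's direction were above. Too few genes were measured to test erythroid (3), adrenal (3), pancreas (4), female-biased (4), renin angiotensin (3) and skeletal muscle markers (2). On the probe set standing for each gene, 0 of these genes was called. The muscle gene Myh1 differed by -0.10 there (adjusted p = 0.579), but its other probe sets did not all follow. In limma over all probe sets they differed by -0.79 (adjusted p = 0.000391), -0.52 (adjusted p = 0.0288), -0.28 (adjusted p = 0.0488) and -0.08 (adjusted p = 0.691).

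The liver dose trend gave 208 calls, 76 rising and 132 falling with the dose rank. Tm7sf2 rose by 0.13 per rank (SE 0.02, adjusted p = 4.46e-05), Gpt by 0.18 (adjusted p = 0.000143), Cyp3a18 by 0.10 (adjusted p = 0.000731), Cyp3a23-3a1 by 0.10 (adjusted p = 0.00101) and Ces2c by 0.13 (adjusted p = 0.0032). A slope per rank does not show a change at every dose. Cyp3a23-3a1 arrays lay at 12.39 to 12.65 in controls, at 12.46 to 12.68 at 100 mg/kg and at 12.85 to 13.06 at 300 mg/kg. The falls with the smallest p ranged from 0.04 to 0.09 per rank. Erlec1, a lectin of the endoplasmic reticulum, fell by 0.05 per rank (adjusted p = 0.0023), and the peroxiredoxin Prdx4 by 0.04 (adjusted p = 0.0035). Clec4a3, a C-type lectin of myeloid cells, fell by 0.09 (adjusted p = 0.0035), Nrep by 0.08 (adjusted p = 0.00427) and the growth hormone receptor Ghr by 0.05 (adjusted p = 0.006). At 500 mg/kg Ghr differed by -0.30, but its other probe set by -0.05. With dose in mg/kg as a linear term the count was 813, with 309 rising and 504 falling, and without the third array at 500 mg/kg it was 80.

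Both genes that rose at 300 mg/kg in liver, Cyp3a23-3a1 and Tm7sf2, were among the 55 that rose at 500 mg/kg. The gene that fell at 300 mg/kg was not among the 53 that fell. Across genes, which are not independent replicates, the log2 changes at 300 and 500 mg/kg correlated with r = 0.650 in liver. Unchanged groups simulated against the same controls gave 0.440 on average, and splitting the controls between the doses gave 0.314. The simulation drew each gene independently and so leaves out correlation between genes. It does not show how far chance could move r. The covariance was 0.0174 against a simulated 0.00775. In kidney the correlation was 0.620, against 0.446 simulated and 0.183 with split controls (0.00104 to 0.334 over 10 splits, against 0.269 to 0.353 in liver), and the covariance 0.0130 against 0.00762. Without both kidney arrays of high adipose transcripts the correlation was 0.518, against 0.374 simulated and 0.03 (0.0277) with split controls (-0.125 to 0.170), and the covariance 0.00836 against 0.00631. In kidney the 1 gene called higher at 300 mg/kg was not among the 3 called higher at 500 mg/kg. With 0 genes called lower at 500 mg/kg, the overlap of lower calls could only be 0. So few calls do not show that the doses share no change.

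In kidney, 0 genes passed limma's adjusted test at 0.1, 1, 10 or 100 mg/kg. At an unadjusted p under 0.05 there were 912, 1045, 703 and 539 genes in that order, against 560 by chance. Array quality weights gave 6 calls at 0.1 mg/kg. The values with the smallest p follow. Ccn2, a matrix-associated growth factor, was at 10.19 ± 0.24 (SD, n = 5) in controls and differed by -0.80 (adjusted p = 0.147) at 0.1 mg/kg and by -0.75 (adjusted p = 0.36) at 10 mg/kg. Tmem163 differed by 0.59 (adjusted p = 0.147) and the laminin gene Lama3 by 0.55 (adjusted p = 0.195) at 0.1 mg/kg. At 1 mg/kg the values were 0.32 for endoglin, Eng, 0.36 for Trpv4 and 0.33 for Nup188 (adjusted p = 0.341 for each). At 10 mg/kg Rundc3b differed by 0.75 (adjusted p = 0.112) and Cdk18 by 0.37 (adjusted p = 0.447). At 100 mg/kg the cell cycle genes Ccnb1 and Cdca3 differed by 0.61 (adjusted p = 0.628) and 0.56 (adjusted p = 0.977), and Ccdc68 by 0.71 (adjusted p = 0.977).

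At 300 mg/kg the kidney showed 3 calls. Proc, the anticoagulant protein C, fell by 0.51 (SE 0.09), from 8.77 ± 0.14 (SD, n = 5) to 8.26 ± 0.06 (SD, n = 4). Asap2 fell by 0.33 (SE 0.06), and the aldo-keto reductase Akr1e2 rose by 0.26 (SE 0.05). The adjusted p was 0.028 for all 3, on 4 of 4 arrays each. Leaving out any single array of the compared groups left 0 calls or 1. At an unadjusted p under 0.05 there were 643 genes, the called ones included, against 560 by chance.

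Replicate 3 at 300 mg/kg and replicate 3 at 500 mg/kg carried high adipose transcripts in the kidney. Ucp1, the uncoupling protein of brown fat, was at 4.55 ± 0.17 (SD, n = 5) in controls, at 13.80 on the first of these arrays and at 12.41 on the second. Fabp4 was at 6.86 ± 0.95 in controls and at 13.34 and 12.44 on these arrays. Without both arrays the kidney had 0 calls at 300 mg/kg, 2 at 500 mg/kg and 0 for the dose trend. At 300 mg/kg the values of Proc and Asap2 stayed near those with all arrays while fewer arrays were left. Proc went from -0.51 (SE 0.09) to -0.52 (SE 0.10) and Asap2 from -0.33 (SE 0.06) to -0.33 (SE 0.07). Akr1e2 went from 0.262 (SE 0.0461) to 0.217 (SE 0.0435), a smaller value without a larger SE. The adjusted p in limma was 0.208 for each.

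At 300 mg/kg the preset camera test called 5 kidney lists, and 0 passed with an estimated correlation or with fry, which had 0 at an unadjusted p under 0.05 as well. Without both arrays of high adipose transcripts 2 passed. Of 33 PPAR alpha targets and fatty acid oxidation genes 0 were called, or 4 higher and 1 lower adjusted over the list alone (median 0.19, adjusted p = 8.63e-08, adjusted p = 0.641 with an estimated correlation). Without both arrays their median was 0.02 (adjusted p = 0.397). For the 15 fatty acid synthesis genes the median was 0.11 (adjusted p = 0.00893, adjusted p = 0.641 with an estimated correlation) and without both arrays -0.03 (adjusted p = 0.852). For the 6 adipose markers it was 1.12 (adjusted p = 0.0064, adjusted p = 0.641 with an estimated correlation) and without both arrays -0.13 (adjusted p = 0.852). Interferon response genes had a median of 0.27 (adjusted p = 6.88e-05, adjusted p = 0.641 with an estimated correlation), and 0.16 without both arrays (adjusted p = 0.0597). Of 32 cell cycle genes 0 were called (median -0.09, adjusted p = 0.0064, adjusted p = 0.770 with an estimated correlation), with -0.08 without both arrays (adjusted p = 0.0369, adjusted p = 0.915 with an estimated correlation). The other list past the preset test without both arrays was male-biased genes (median -0.30, adjusted p = 0.0369, adjusted p = 0.369 with an estimated correlation).

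At 500 mg/kg the kidney showed 3 calls, 3 higher and 0 lower. Dnase1, a secreted nuclease, rose by 0.87 (SE 0.14, adjusted p = 0.00881), from 10.71 ± 0.29 (SD, n = 5) to 11.58 ± 0.21 (SD, n = 4). Hpd, a dioxygenase of tyrosine breakdown, rose by 0.48 (SE 0.07, adjusted p = 0.00104), from 12.10 ± 0.07 to 12.59 ± 0.15. Part of this distance from control was seen at lower doses, where Hpd was not called. Its arrays lay at 12.18 to 12.38 at 0.1 mg/kg and at 12.32 to 12.40 at 300 mg/kg. Yars2, the mitochondrial tyrosyl-tRNA synthetase, rose by 0.35 (SE 0.07, adjusted p = 0.0465). Each was higher on 4 of 4 arrays. Without both arrays of high adipose transcripts Dnase1 and Hpd were called, at 0.91 (adjusted p = 0.0267) and 0.42 (adjusted p = 0.0175), and Yars2 was not, at 0.35 (SE 0.07, adjusted p = 0.192). At an unadjusted p under 0.05 there were 1073 genes against 560 by chance. The number of calls was 0 with only the compared groups in the fit, 34 without the first control array, 18 with quantile normalization within the organ (9 higher and 9 lower) and 69 with array quality weights (46 higher and 23 lower).

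**Figure D3:**
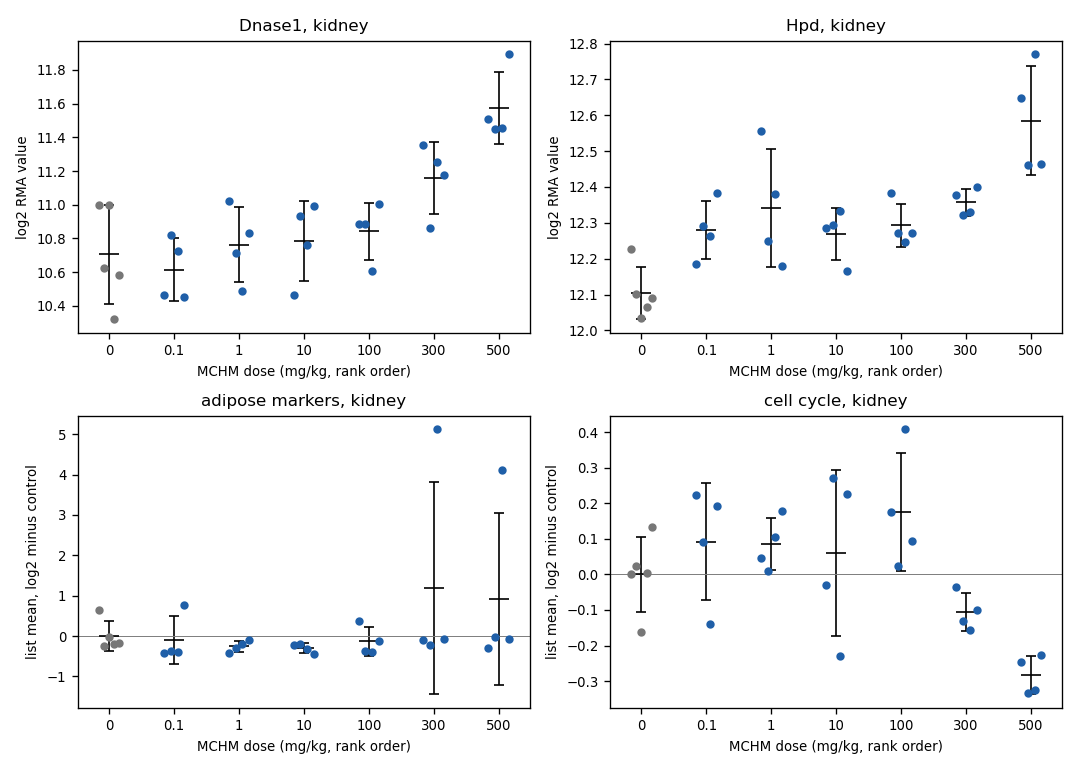
Kidney log2 RMA values of Dnase1 and Hpd, and the means of the adipose and cell cycle lists on each array as log2 minus the control mean, by MCHM dose in mg/kg drawn in rank order. Points are arrays (grey 0 mg/kg, blue dosed) and bars the mean ± SD; 1 array at 300 mg/kg and 1 at 500 mg/kg lie far above the others for adipose markers, and all 4 arrays at 500 mg/kg lie below 0 for the cell cycle.

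The preset camera test called 5 kidney lists at 500 mg/kg, of which 0 passed with an estimated correlation (5 of 27 lists at an unadjusted p under 0.05) and 3 with fry. Of 32 cell cycle genes 0 were called, or 9 lower adjusted over the list alone, and 3 had a value above 0 (median -0.29, adjusted p = 2.9e-17, adjusted p = 0.104 with an estimated correlation, fry adjusted p = 0.0416). Ccnb2 differed by -0.64 (adjusted p = 0.0831), Cdk1 by -0.58 (adjusted p = 0.112) and Kif20a by -0.54 (adjusted p = 0.133). All 20 cholesterol genes had a value above 0, with 0 called, or 2 adjusted over the list alone (median 0.14, adjusted p = 9.99e-05, adjusted p = 0.155 with an estimated correlation, fry adjusted p = 0.0416). Mvd differed by 0.30 (adjusted p = 0.232) and Insig1 by 0.40 (adjusted p = 0.335). Of 23 Nrf2 targets 0 were called, or 3 lower adjusted over the list alone (median -0.07, adjusted p = 9.99e-05, adjusted p = 0.104 with an estimated correlation, fry adjusted p = 0.0416). Gstp1 differed by -0.88 (adjusted p = 0.0791), Akr1b8 by -0.77 (adjusted p = 0.0775) and Gstm1 by -0.52 (adjusted p = 0.322).

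Of 14 macrophage and lymphocyte markers in kidney at 500 mg/kg 0 were called, or 1 lower adjusted over the list alone, and 0 had a value above 0 (median -0.12, adjusted p = 0.000257, adjusted p = 0.104 with an estimated correlation). Adgre1 and Ptprc differed by -0.48 (adjusted p = 0.189) and -0.35 (adjusted p = 0.322). The PPAR alpha list had a median of 0.14 (adjusted p = 0.0424, adjusted p = 0.719 with an estimated correlation), and without both arrays of high adipose transcripts 0.00 (adjusted p = 0.568). Cyp4a1 differed by 0.54 (adjusted p = 0.0792) and Cpt1a by -0.33 (adjusted p = 0.0918). The cholesterol, Nrf2, cell cycle and macrophage and lymphocyte lists had adjusted p of 0.000317, 0.0011, 3.47e-16 and 0.000529 without both arrays, and none passed with an estimated correlation there (adjusted p = 0.289 for cholesterol and 0.164 for the others). The fifth list past the preset test without both arrays was the stress response (median -0.07, adjusted p = 0.0314, adjusted p = 0.325 with an estimated correlation).

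Among the kidney lists that did not pass at 500 mg/kg, injury markers had a median of -0.02 (adjusted p = 0.406). Tff3 differed by -0.90 (adjusted p = 0.241) and Clu by 0.32 (adjusted p = 0.385). The medians were 0.06 for proximal tubule (mean -0.03, adjusted p = 0.641), 0.04 for distal tubule and collecting duct (adjusted p = 0.641) and 0.16 for glomerular markers (adjusted p = 0.406). Fatty acid synthesis had a median of 0.21 (adjusted p = 0.406), with Fads1 at 0.67 (adjusted p = 0.0791) and Me1 at -0.47 (adjusted p = 0.0775). The mean of this list lay above the control on 1 dosed array. Its median was 0.0254 without both arrays of high adipose transcripts (camera adjusted p = 0.9575). Adipose markers had a median of 0.87 (adjusted p = 0.313), with 1 of 4 arrays above the control in the list mean. Without both arrays of high adipose transcripts their median was -0.084 (camera adjusted p = 0.561). Male-biased genes had a median of -0.67 (adjusted p = 0.0578), and of -0.33 without both of those arrays (camera adjusted p = 0.151). The median was 0.15 for the circadian clock (adjusted p = 0.11) and -0.05 for alcohol and aldehyde oxidation (adjusted p = 0.313), where Cyp2e1 differed by 0.60 (adjusted p = 0.101). For conjugation genes the median was -0.05 (adjusted p = 0.95), with Acsm1 at 0.53 (adjusted p = 0.0831). It was -0.01 for CAR and PXR targets (adjusted p = 0.313), -0.07 for AhR targets (adjusted p = 0.406) and 0.05 for interferon response genes (adjusted p = 0.987, camera direction down). It was -0.02 for the stress response (adjusted p = 0.406), 0.02 for p53 targets (adjusted p = 0.687, camera direction down), -0.05 for acute phase (adjusted p = 0.459) and -0.04 for immediate early genes (adjusted p = 0.406). It was -0.03 for bile acid genes (adjusted p = 0.406), 0.06 for endothelial and stromal markers (adjusted p = 0.95) and 0.01 for pericentral genes (adjusted p = 0.949). It was -0.02 for periportal genes (adjusted p = 0.406) and -0.00 for glucose metabolism (mean 0.01, adjusted p = 0.595). Erythroid, adrenal, pancreas, female-biased, renin angiotensin and skeletal muscle markers had under 5 measured genes.

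The kidney dose trend gave 17 calls, 13 rising and 4 falling. Dnase1 rose by 0.13 per dose rank (SE 0.02), Hpd by 0.06, the alpha-mannosidase Man2c1 by 0.04 and the elongation factor Elof1 by 0.03 (adjusted p = 0.0176 for each), and Zswim7 by 0.10 (adjusted p = 0.0284). At 500 mg/kg Man2c1 differed by 0.245, and its other probe sets by 0.154 and 0.026. Proc fell by 0.09 per rank and Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, by 0.06 (adjusted p = 0.034 for both). These slopes do not show a change at every dose. Proc arrays lay at 8.55 to 8.90 in controls, at 8.57 to 8.93 at 100 mg/kg and at 8.17 to 8.30 at 300 mg/kg. Those of Hpd lay at 12.03 to 12.23 in controls and already at 12.18 to 12.38 at 0.1 mg/kg. The aldo-keto reductase Akr1b8 fell by 0.13 (adjusted p = 0.0452) and the adenine nucleotide carrier Slc25a4 by 0.03 (adjusted p = 0.0491). The count was 0 without both arrays of high adipose transcripts or without the first array at 500 mg/kg, and 54 without the third control array. All 17 slopes kept their sign without both arrays and without the first array at 500 mg/kg, at a median of 0.914 and 0.959 of their size. The ranges were 0.767 to 1.12 and 0.917 to 1.06, with adjusted p of 0.0557 to 0.271 and of 0.0770 to 0.125. Dnase1 was at 0.12 per rank (SE 0.02) without both arrays and at 0.13 (SE 0.02) without the first array at 500 mg/kg. The balance of rising and falling calls depended on the term, since dose in mg/kg as a linear term gave 185 calls, 86 rising and 99 falling. The trend genes named here kept their sign with that term.

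The 500 mg/kg effect differed between liver and kidney for 13 genes, 11 with the higher value in liver and 2 in kidney. Acly rose in liver and differed by -0.17 in kidney, a difference of 1.08 (SE 0.23, adjusted p = 0.0204). Acsm2 differed between the organs by 1.03 (SE 0.23, adjusted p = 0.044). Me1, which supplies NADPH for lipid synthesis, was at 0.41 in liver and at -0.50 in kidney, a difference of 0.91 (SE 0.19, adjusted p = 0.0197). Sectm1b differed by 0.86 (SE 0.17, adjusted p = 0.0129) and the transcriptional regulator Hes6 by 0.86 (SE 0.18, adjusted p = 0.0204). Tfpi, an inhibitor of tissue factor, was at -0.45 in liver and 0.19 in kidney, a difference of -0.65 (SE 0.12, adjusted p = 0.00921). Aph1a, a gamma-secretase subunit, had a difference of -0.33 (SE 0.07, adjusted p = 0.0344). The count was 5 without both kidney arrays of high adipose transcripts, 0 with only the compared groups in the fit, 4 without the fourth liver array at 500 mg/kg and 54 without the first kidney control array. The balance of directions moved as well, to 20 higher in liver and 17 in kidney with a random block of dose and replicate number (37 genes), and to 37 and 47 with array quality weights (84 genes). At 300 mg/kg 0 genes passed in limma, with 587 at an unadjusted p under 0.05 against 534 by chance. The smallest p there belonged to Sqstm1, with a difference of 0.44 (adjusted p = 0.171), Asap2, with 0.57 (adjusted p = 0.171), and Proc, with 0.44 (adjusted p = 0.252).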

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

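Chosen only after the result was seen were the tests of a dose effect on every kidney, of another organ under a kidney label and of the share of the main cell type in both organs, the fit without 2 kidney arrays and the macrophage and lymphocyte list without RT1-Ba.

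Of 119 groups of arrays tested with Dixon's ratio, 14 held an array far from the others, where chance gives about 1 in 20. Each value is the log2 distance of that array from the mean of the other arrays of its group. In liver, replicate 2 at 500 mg/kg stood apart for Ccnd1 (-0.59) and Gpt (0.37), control replicate 4 for Nusap1 (0.48) and control replicate 2 for Spmip11 (0.53). In kidney at 500 mg/kg, replicate 4 stood apart for Dnase1 (0.42) and replicate 2 for Yars2 (0.019). The mean of the kidney macrophage and lymphocyte list did so on replicate 1 at 300 mg/kg (-0.29). Kidney control replicate 1 stood apart for the means of the fatty acid synthesis list (0.59) and the adipose list (0.80).

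Replicate 3 at 300 mg/kg and replicate 3 at 500 mg/kg stood apart in kidney for the means of the adipose list (5.25 and 4.26) and the fatty acid synthesis list (1.28 and 0.78). The first of these arrays did so for the PPAR alpha list as well (0.88). On them Ucp1 lay 9.24 and 7.85 above the control mean, Cfd 6.99 and 5.68, Adipoq 5.05 and 3.85, and Lep -0.11 and -0.04. The control means of Ucp1, Cfd and Adipoq (4.55, 4.12 and 4.98) lay below the medians of the arrays, so these distances are not exact folds.

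The tables argue against an effect of the dose on every kidney, since the highest adipose list mean on the other 6 arrays at both doses was -0.03 (-0.028). They argue against a sample of another organ, since the lower proximal tubule list mean of both arrays was -0.17. Brown adipose tissue in these 2 samples may account for the pattern, but the test set for it in advance missed its bound: over 10 brown adipose markers the medians were 0.59 and 0.28 (0.2777), and a median under 0.5 on either array was to count against it. It is left open, for a reason found only after the result was seen, because the markers go apart. Cox8b (7.81 and 6.49), Adrb3 (3.07 and 1.751) and Slc36a2 (3.71 and 2.92) each lay over 1 above every other kidney array. Cox7a1 (0.30 and 0.54), Prdm16 (-0.16 and -0.29), Zic1 (-0.18 and 0.01), Kcnk3 (-0.08 and -0.17), Ebf2 (0.93 and 0.67), Dio2 (0.88 and 0.02) and Elovl3 (-0.03 and -0.06) did not. The miss was not tested against the spread of the markers. Of the 10 markers 3 passed the filter in kidney, Cox7a1, Prdm16 and Kcnk3, and 3 others, Ebf2, Dio2 and Elovl3, had control means under 3. Cox8b, Adrb3 and Slc36a2 did not pass the filter, which asks for 4 arrays and need not be met by a marker high on these 2 alone. Their control means of 4.14, 4.04 and 3.50 were near background, so their distances are not exact folds either. Among the tested explanations only the effect of the dose is a biological one.

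Macrophage and lymphocyte markers had lower list means at 500 mg/kg in both organs, by 0.32 in liver (exact permutation p = 0.00794, the smallest possible) and by 0.23 in kidney (exact permutation p = 0.0238), and neither passed the adjustment over 27 lists (adjusted p = 0.107 and 0.214). Both rest in part on RT1-Ba (-2.06 and -1.34), whose 3 other probe sets differed by 0.02 to 0.56 in liver and by -0.07 to 1.19 in kidney: without this gene the means were lower by 0.22 (exact permutation p = 0.0556) and 0.15 (exact permutation p = 0.0952). A larger share of the main cell type could lower endothelial and stromal markers alike, and these differed by -0.13 in liver and 0.03 in kidney. The gap between both lists moved with an exact permutation p of 0.127 in liver and 0.0635 in kidney (0.524 and 0.198 without RT1-Ba), which does not decide. The kidney values include an array of high adipose transcripts. Without both such arrays the kidney medians were -0.035 for endothelial and stromal and -0.074 for macrophage and lymphocyte markers. The gap was not tested without them. A glucocorticoid response may also lower lymphocyte transcripts, and the mean of 13 glucocorticoid responsive genes differed by 0.04 (0.0352) in liver (exact permutation p = 0.667) and by 0.03 (0.0288) in kidney (exact permutation p = 0.643). These explanations and a direct effect of the dose on these cells cannot be told apart with 4 arrays against 5, since none of these 4 tests passed or excluded its explanation.

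By the test of the difference itself, the 500 mg/kg effect differed between liver and kidney for 13 genes, a count that ranged from 4 to 54 with single arrays left out and was 37 with a random block of dose and number and 84 with array quality weights. Those named were Acly (1.08), Acsm2 (1.03), Me1 (0.91), Sectm1b (0.86), Hes6 (0.86), Tfpi (-0.65) and Aph1a (-0.33), as liver minus kidney on the log2 scale. Among probe sets with no gene name, which the comparisons of genes did not use, 22 of 4342 were called in liver at 500 mg/kg, 6 higher and 16 lower, and 1 of 4153 in kidney, higher.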

How the results depend on the processing

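Chosen only after the data were seen were the fit without both kidney arrays of high adipose transcripts and the random block of dose and number. Of 171 gene results under 3794 alternatives, 3373 kept their direction and side of the threshold, 368 no longer passed it, 45 newly passed it and 8 reversed. Genes that had not passed in the main fit count as kept while they stay uncalled. The share kept therefore does not measure how stable the calls were. Among called genes, Ccnd1 in liver at 500 mg/kg lost its call in 13 of 19 alternatives and Gpt in 0. In kidney at 300 mg/kg Proc and Asap2 lost theirs in 13 of 20 and Akr1e2 in 12. The cause was not tested unless stated, an array has no depth to vary, and scaling alternatives moved the median of all genes by under 0.1.

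Array quality weights gave 1 call in liver at 10 mg/kg, 263 at 500 mg/kg, and in kidney 6 at 0.1, 0 at 300 and 69 at 500 mg/kg, 45 for the trend and 84 for the difference between organs at 500 mg/kg. Only the compared groups in the fit, with fewer arrays, gave 2, 1 and 65 in liver at 10, 300 and 500 mg/kg, 0 in kidney at 300 and at 500 mg/kg and 0 for the difference. EBayes without the trend gave 58 in liver at 500 mg/kg and 0 in kidney at 300 mg/kg. The replicate number as a block gave 0 and 33 in liver at 300 and 500 mg/kg, 1 in kidney at 300 mg/kg and 6 for the kidney trend. A 1.5-fold minimum, stricter by construction, gave 34 in liver at 500 mg/kg, 0 and 1 in kidney at 300 and 500 mg/kg and 8 for the difference. Quantile normalization within the organ gave 18 in kidney at 500 mg/kg, 32 for the kidney trend and 21 for the difference. Cyclic loess gave 29 for the kidney trend and 20 for the difference. All probe sets gave 0 in kidney at 300 mg/kg and 21 for the difference, and a stricter filter gave 25 for the difference. Dose as a linear term gave 813 for the liver and 185 for the kidney trend. The random block gave 37 for the difference.

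Without both kidney arrays there was 1 call in kidney at 0.1 and 1 at 10 mg/kg, 0 at 300 mg/kg and 0 for the trend, 5 for the difference and 2 lists at 300 mg/kg. Camera with an estimated correlation gave 0 lists in liver and 0 in kidney at 300 and 500 mg/kg. Fry gave 0 lists at 300 mg/kg in both organs and 3 in kidney at 500 mg/kg, and no filter gave 8 there.

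With each array left out in turn, calls in liver ranged from 0 to 1 at 10 mg/kg (1 without control replicate 5 or replicate 4 at 10 mg/kg) and were 0 throughout at 0.1, 1 and 100 mg/kg. At 300 mg/kg they ranged from 0 without replicate 3 to 6 without replicate 2, with 1 without control replicate 1, 4 or 5. The liver calls at 500 mg/kg ranged from 42 to 108: 42, 55 and 71 without replicates 1, 3 and 4, and 66, 62 and 43 without control replicates 2, 4 and 5. The liver trend ranged from 80 to 255, with 91, 80 and 100 without replicates 1, 3 and 4 at 500 mg/kg. Kidney calls ranged from 0 to 1 at 0.1 (1 without control replicate 1), at 10 (1 without replicate 1 at 10 mg/kg) and at 300 mg/kg (any array), and were 0 throughout at 1 and 100 mg/kg. At 500 mg/kg they ranged from 2 to 34: 34 and 7 without control replicates 1 and 3, 11 and 6 without replicates 2 and 4. The kidney trend ranged from 0 without replicate 1 at 500 mg/kg to 54 without control replicate 3. It was 11 and 10 without control replicates 2 and 5, 5 and 10 without replicates 1 and 4 at 0.1 mg/kg, 8 without replicate 2 at 1 mg/kg, 10, 9, 6 and 5 without each replicate at 300 mg/kg, and 9, 3 and 6 without replicates 2, 3 and 4 at 500 mg/kg. Lists ranged from 6 to 7 and 5 to 9 in liver at 300 and 500 mg/kg, from 2 (without control replicate 5 or replicate 3) to 7 in kidney at 300 mg/kg and from 4 to 7 at 500 mg/kg. The difference between organs ranged from 0 to 1 at 300 mg/kg (1 without liver control replicate 4) and from 4 to 54 for the liver minus kidney difference of the 500 mg/kg effect. There it was 54 without kidney control replicate 1, 6, 25, 5 and 31 without kidney replicates 1 to 4, 26, 8 and 4 without liver replicates 2, 3 and 4, and 6 without liver control replicate 4.

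None of the reversed values had passed the threshold. Hnf4a in kidney was at 0.10 with the mean over its probe sets. With each array left out in turn Psmb8 in liver at 500 mg/kg ranged from -0.012 without replicate 4 to 0.38. In kidney, Ucp1 ranged from -0.00504 to 2.63, Cfd from -0.20 to 1.80 and Adipoq from -0.16 to 1.20, each lowest without replicate 3 at 500 mg/kg and at that same value without both kidney arrays.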

Other observations

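Chosen only after the result was seen was the correlation of interferon list means between organs, as was the reading of the batch test by organ and against its spread, while the test of the same rat and the splits of the arrays were set in advance.

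Below 300 mg/kg the preset camera test called lists although 0 genes were called in limma. In liver these were 1, 7, 5 and 2 of 27 lists at 0.1, 1, 10 and 100 mg/kg, and in kidney 0, 3, 1 and 1. In kidney at 0.1 mg/kg 6 lists had an unadjusted p under 0.05. With an estimated correlation 0 lists passed at any of these doses, with 1, 4, 3 and 1 in liver and 2, 1, 2 and 0 in kidney at an unadjusted p under 0.05. Fry called 2 lists, both in liver at 1 mg/kg, bile acid synthesis and transport (median 0.12, adjusted p = 0.0432) and p53 targets (median -0.15, adjusted p = 0.00856). The bile acid list was past the preset test in liver at 0.1, 1 and 10 mg/kg, with medians of 0.12 each (adjusted p = 0.0964, 0.0786 and 0.272 with an estimated correlation). Cholesterol genes had a median of 0.20 at 1 mg/kg and of 0.18 at 100 mg/kg in liver (adjusted p = 0.372 and 0.999 with an estimated correlation), but of -0.06 (-0.061) at 10 mg/kg, where the preset test did not call them (adjusted p = 0.0936). Fatty acid synthesis genes, called at both doses by the preset test, had a median of 0.24 at 1 mg/kg and of -0.15 at 10 mg/kg in liver (adjusted p = 0.372 and 0.418 with an estimated correlation), so neither list kept 1 direction. Cell cycle genes had a median of -0.18 at 10 and at 100 mg/kg in liver (adjusted p = 0.351 and 0.999 with an estimated correlation) and of 0.22 at 100 mg/kg in kidney (adjusted p = 0.536 with an estimated correlation).

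The mean of the interferon response list in a liver and in the kidney of the same dose and replicate number correlated over 29 such pairs, with Pearson's r = 0.819 and Spearman's rho = 0.789 (permutation p = 1e-05 for both, the smallest the permutations can give; r = 0.746 without the 2 samples farthest from the median). The same rat behind a liver and a kidney of equal number is a candidate explanation: over genes outside that list, 26 of the 29 livers correlated best with the kidney of their own number among those of their dose (mean correlation 0.135 against -0.044 for other numbers, permutation p = 1e-05, the smallest possible). Deviations from the group means were correlated, so the value below 0 for other numbers follows largely from the own value and is no separate result. A correlation over 0.1 was seen in 21 of the 29 pairs, and the labels do not state the pairing, so the comparisons treat the organs as separate animals. The tables argue against a processing batch that follows the replicate number in liver, where arrays of equal number at different doses correlated by -0.01 (-0.00887) more than others (SD of permuted differences 0.0169, permutation p = 0.674). In kidney the difference was 0.04 (0.0381, SD of permuted differences 0.0238, permutation p = 0.0678), which lies within its spread of the bound of 0.05, so such a batch there stays open.

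Over 100 splits of the same arrays, the real one included, only the real one reached 3 liver calls at 300 mg/kg (highest other 2). The same held at 500 mg/kg (108, highest other 3) and for the dose trend (208, highest other 2), each with 1 split as large. Counts of 3 against 2 are too close to exclude chance at 300 mg/kg. No adjustment was made over the counts tested in this way. The liver count at 300 mg/kg was 0 without replicate 3 at 300 mg/kg or with the replicate number as a block, and 1 without control replicate 1, 4 or 5, while over all alternatives Tm7sf2 stayed at 0.69 to 0.77, Cyp3a23-3a1 at 0.46 to 0.53 and Lmcd1 at -0.87 to -0.65. In kidney only the real split reached 3 calls at 300 mg/kg (highest other 2), again too close to exclude chance. For the kidney dose trend it alone reached 17 (highest other 1). Both counts were 0 without both arrays of high adipose transcripts. The trend was also 0 without replicate 1 at 500 mg/kg, and the count at 300 mg/kg was 0 or 1 without any single array. Without both arrays Proc at 300 mg/kg moved from -0.51 to -0.52, and Asap2 stayed at -0.33. The loss of these 2 calls does not show that they came from the arrays left out. Akr1e2 shrank from 0.262 (SE 0.0461) to 0.217 (SE 0.0435), so its call may rest in part on them. The 17 slopes had a median of 0.914 of their size, with a range of 0.767 to 1.12. The loss of the trend calls does not decide where they came from. For the difference between organs at 500 mg/kg (13, highest other 4) 1 split was as large, but the count was 4 without liver replicate 4 at 500 mg/kg, 5 without both adipose arrays, 0 with only the compared groups and 37 with a random block of dose and number, and the splits do not use the pairing of organs. For kidney calls at 500 mg/kg chance was not excluded, since 7 of 100 splits gave at least the 3 real calls, with 287 as the highest other. For 0 calls all 100 splits gave as many: the highest other was 1, 1, 3 and 2 in liver at 0.1, 1, 10 and 100 mg/kg, 131, 178, 10 and 2 in kidney, and 2 for the difference at 300 mg/kg. Kidney splits with 131, 178 and 287 calls point to a structure of the samples, but what these splits share was not tested, and the counts of splits treat the arrays as exchangeable. For the preset camera lists chance was not excluded: 15 and 38 splits gave as many as the real 7 and 6 in liver at 300 and 500 mg/kg (highest other 9 and 10), and 63 and 76 as many as the real 5 and 5 in kidney (highest other 11 and 10).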
